A study of Danio rerio with 4 samples.

How the data were processed

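The study measured single-cell RNA from the sinus venosus (SV) and bulbus arteriosus (BA) of adult WT zebrafish and nr2f1a mutants, in 4 libraries with 1 library per group. Per the labels' protocols, pooled tissue was dissociated with enzymes at warm temperature, libraries were made with the 10x Genomics Chromium 3' v2 assay and sequenced on an Illumina HiSeq 4000. How many fish were pooled per library is not given in the sources used here. Per the submitters' processing notes, Cell Ranger 3.1.0 was used, and the builds GRCz11 and hg19 are listed with no role. The settings of that step are not given in the sources used here.

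The deposited matrices hold whole-number UMI counts per gene and barcode, which the authors had not normalised. They have 32057 features with 31326 symbols; counts of the 545 symbols shared by several features were added. A deposited cluster table gives each kept barcode a library, 1 of 15 clusters and a cluster name. It names 29195 of 53274 barcodes; the rule by which the authors kept them is not given in the sources used here. The remaining 24079 barcodes (6469 in WT SV, 6633 in mutant SV, 4314 in WT BA and 6663 in mutant BA) have median UMIs of 1130, 938, 1347 and 917, and enter only the check of nr2f1a and the closing observations. The kept cells were used as deposited with no further filter. Of them 192, 76, 52 and 27 exceeded 10% mitochondrial UMIs.

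UMIs of a cluster and library were summed and divided by their total to give CPM. A ratio is that of 2 CPM values, with an exact conditional binomial (Clopper-Pearson) 95% interval; counts have exact Poisson intervals and shares Clopper-Pearson intervals. All cover counting error only. For ranking and for lists, the lower value was set to at least 3 counts, and a ratio against 0 counts is given as a lower bound from that floor. Clusters were compared where both libraries had at least 100 cells.

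The design, the gene lists, the markers, the rule for named genes and most alternatives were set before the data were examined. A gene was named in a comparison if it had at least 50 CPM and a UMI in at least 10% of cells in the higher library, and at least 0.2 of the CPM of that library's highest cluster of at least 50 cells. Of these, the genes of largest ratio were taken: 12 each way in cluster 10 and cluster 4 of the SV, 8 each way in the muscle and arterial clusters of the BA and between WT tissues, and 5 each way elsewhere. Genes known only by a clone or similar identifier were passed over. Other genes in the text are list members or cell type markers. Genes with a near-identical copy may share UMIs, since the rule for such reads is not given in the sources used here.

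There were 28 gene lists. A member counted as measured at 20 or more summed UMIs over both libraries, and medians needed at least 3 members. Each median was ranked among 10000 random lists of the same size drawn from the same deciles of mean CPM, and its bounds are the 2.5 and 97.5 percentiles of 200 Poisson redraws. Which lists the text describes was chosen after their medians were seen, as were the comparison of clusters by number and the limits for singling out differences between tissues.

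To place mutant SV between the tissues, WT SV cells were split at random into parts A and B. Genes at 50 CPM or more and at least 2-fold apart between part A and WT BA formed the BA-high and SV-high lists, which were measured as mutant SV over part B.

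Doublets were scored with scrublet as run in scanpy. Its automatic threshold marked 1.75% of barcodes in WT SV, 0.856% in mutant SV, 0.0154% in WT BA and 0.419% in mutant BA, so it did not work in all libraries. The highest scores were therefore marked at 0.8% per 1000 barcodes, a rule set after this was seen. It marked 9.38%, 9.00%, 11.3% and 13.6% of kept cells, which stayed in the main results and were left out in an alternative. No correction for free RNA was made in the main results; acta2 was seen in 47.3% of WT SV and 50.8% of mutant SV endothelial cells of cluster 4, at 215 and 162 CPM.

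The alternatives were scaling by TMM (trims 0.3 and 0.05) or median-of-ratios factors of the sums, totals without haemoglobin, mitochondrial and ribosomal protein genes, a mean over cells, and cells thinned to 3000 UMIs. Thinning left out 500, 432, 462 and 385 cells of WT SV, mutant SV, WT BA and mutant BA. Others were leaving out marked doublets or cells over 10% mitochondrial UMIs, subtraction of an ambient profile, random parts of the cells, other minimums, 20 other splits and own clusters. The ambient profile was the library mean scaled to the haemoglobin of the cluster and capped at 0.5 of its UMIs. This is a weak estimate, because haemoglobin stood at 11.0% of the library level in WT cluster 10 but at 26.6% in mutant cluster 10 and at 128% in mutant cluster 39. Own clusters came from counts scaled to 10000 per cell, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5, without integration.

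The ratio, list and placement steps were tested on simulated counts drawn from the real means and totals with 200 genes changed. For mutant over WT SV in cluster 10 (1385 genes) the interval held the true ratio in 95.1% of genes, in cluster 4 (1403 genes) in 95.2%, in cluster 38 (1506 genes) in 95.4%, and for mutant over WT BA in cluster 36 (1580 genes) in 95.2%. Of genes changed by at least 1.5 on the log2 scale, 100%, 100%, 91.3% and 100% were found at 2-fold in the right direction, and 0, 0, 3 and 0 unchanged genes reached 2-fold. The placement slope came out at 0.300 for a true slope of 0.3. The simulated counts were Poisson, with no spread between cells or libraries, so this coverage was built in and does not test the intervals on real cells. In random parts of the real cells, 115 and 118 values of genes and lists named in passing left their interval, and 246 and 243 stayed within it.

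The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.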

Results

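Single-cell RNA profiles were compared for 2 parts of the adult zebrafish heart, each from wild-type (WT) fish and from nr2f1a mutants. The sinus venosus (SV) is the venous inflow chamber of the heart, and the bulbus arteriosus (BA) is its elastic, smooth-muscle-rich outflow chamber. nr2f1a encodes an orphan nuclear receptor known to maintain atrial identity. The 4 libraries were WT SV, mutant SV, WT BA and mutant BA, and each group had 1 library. The matrices held 13439, 12736, 13004 and 14095 barcodes in that order. The deposited cluster table named 6970, 6103, 8690 and 7432 of them as cells, with medians of 7810, 8972, 7389 and 7880 UMIs (unique molecular identifiers, that is, counted RNA molecules). Only these 29195 cells enter the comparisons, in the 15 clusters of the deposited table.

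Cells of a library are not replicates, so no difference between groups was tested, and no difference carries an estimate of the spread between animals. Values are summed UMIs of a cluster relative to their total, as CPM. Ratios carry exact 95% intervals that cover counting error only. For each gene list fixed before the data were examined, the text gives the median log2 ratio, in places with the members at least 2-fold higher or lower and the percentile of that median among 10000 random lists matched on expression. Because several clusters led by genes of another cell type carried muscle names, clusters are compared by number, with the deposited name as their label.

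Summed over all cells, nr2f1a itself was higher in both mutant libraries. Over all kept cells it reached 32.3 CPM (30.9 to 33.8; 1947 UMIs) in mutant SV against 17.9 CPM (16.8 to 19.0; 1096 UMIs) in WT SV, a 1.81-fold difference (1.68 to 1.95). In the BA it was 5.72 CPM (401 UMIs) in the mutant against 1.79 CPM (125 UMIs) in WT, 3.19-fold (2.61 to 3.93). Of the 401 UMIs, 328 came from the 354 cells of cluster 20. Without that cluster, a choice made after the values were seen, mutant BA was at 1.09 CPM and WT BA at 1.69 CPM (1.55-fold lower, 1.15 to 2.11), so the direction of the BA sum turns without cluster 20. WT SV exceeded WT BA 9.98-fold (8.28 to 12.1). The position of the mutation is not given in the sources used here, and a 3' tag outside the mutated part checks nothing, so these levels say nothing on the genotype labels.

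By cluster, nr2f1a was higher in mutant SV cells of cluster 4, deposited as venous-lymph, at 78.7 against 32.7 CPM (2.41-fold, 2.16 to 2.68). In cluster 10, deposited as smooth muscle, it was 22.7 against 9.72 CPM (2.34-fold, 2.02 to 2.72; 676 and 243 UMIs). Cluster 20, deposited as pan-endothelial and led by genes that include the lymphatic markers mrc1a and prox1a, stood at 122 against 13.8 CPM in the SV (8.87-fold, 3.88 to 25.01) and 107 against 15.6 CPM in the BA (6.90-fold, 3.46 to 16.1). Cluster 9, also deposited as pan-endothelial, was higher in mutant BA too, at 63.9 against 21.05 CPM (3.04-fold, 1.57 to 6.35). The arterial cluster 32 of the BA went the other way, at 0.0881 CPM (1 UMI) in the mutant against 2.12 CPM (14 UMIs) in WT. Muscle clusters of the BA were lower in the mutant in cluster 49 (8.92-fold, 2.18 to 27.35) and cluster 8 (2.58-fold, 1.03 to 8.32), but not in cluster 36 (ratio 1.013, 0.119 to 3.90). Their sum, at 0.474 against 1.54 CPM, also carries the change in the mix of these clusters. In cluster 10, 18.3% of mutant and 7.65% of WT cells had an nr2f1a UMI, at median depths of 9896 and 9017. The epithelial cluster 5 of the same libraries, taken as cells that should lack it, had 23.5% of 17 cells (6.81 to 49.9%) and 10.7% of 150 cells (6.22 to 16.7%), at 13678 and 10640 UMIs. Whether cells of cluster 5 do lack nr2f1a was not tested. Cluster 18 is also deposited as epithelial, but the thyroid follicular marker tg is among its leading genes. It had 0 of 20 mutant cells (0 to 16.8%) and 8.57% of 70 WT cells (3.21 to 17.7%), at 12598 and 11232 UMIs. Cluster 16, looked at after these values were seen, had 3.24% of 247 mutant cells (1.41 to 6.28%) and 3.27% of 214 WT cells (1.33 to 6.62%), at 11503 and 9150 UMIs. The shares in cluster 10 (16.92 to 19.8% and 6.67 to 8.72%) stand above cluster 16 in both libraries and above cluster 18 in the mutant, but not above cluster 5, which has few cells, or WT cluster 18. How much of them is background stays open.

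**Figure D1:**
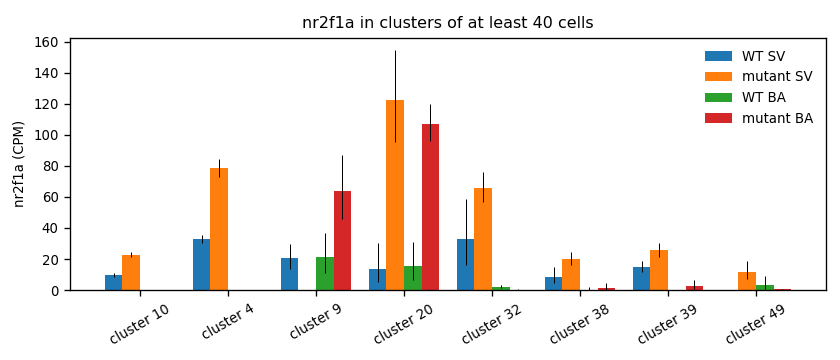
Level of nr2f1a (CPM, linear axis) per deposited cluster and library, for clusters of at least 40 cells in a library. Bars are CPM of summed UMIs in 1 library and error bars are exact 95% Poisson intervals. Cluster 4 stands at 78.7 CPM in mutant SV and 32.7 CPM in WT SV.

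The SV libraries consisted mainly of cluster 10 and of endothelial cells, and the BA libraries mainly of clusters 8, 36 and 49. Cluster 10 held 38.3% of WT SV cells (37.1 to 39.4%) and 48.0% of mutant SV cells (46.7 to 49.2%). The 4 endothelial clusters 32, 4, 9 and 20 held 33.8% of WT SV and 21.02% of mutant SV cells. The venous-lymph cluster 4 held 30.6% (29.5 to 31.7%) and 15.06% (14.2 to 15.98%), and the arterial cluster 32 held 0.617% (43 cells) and 4.34% (265 cells). Cluster 38, deposited as smooth muscle and led by fibroblast genes such as col1a1a, dpt and lum, held 2.84% of WT SV and 8.996% of mutant SV cells. Clusters 8, 36 and 49 held 27 cells (0.387%) of WT SV and 210 cells (3.44%) of mutant SV.

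Among WT BA cells 60.1% fell in cluster 36 and 23.9% in cluster 8, whereas 70.4% of mutant BA cells fell in cluster 49. Cluster 36 came to 95.3% from WT BA and cluster 49 to 92.9% from mutant BA, so each may be a library rather than a cell type. The pan-endothelial cluster 20 held 4.76% of mutant BA against 0.771% of WT BA cells. Genes that define the clusters differ between the groups, so shares can move without a change in cell types. In clusters made anew without integration, the arterial share of the SV was 0.0287% in WT and 0.0655% in the mutant, and that of cluster 49 was 0.0144% and 0.164%, resting on 2, 4, 1 and 10 cells. Cluster 38 held 0 WT and 5 mutant SV cells (0.0819%) there. These clusters split by library: 1 of them took 89.9% of WT and another 95.3% of mutant SV cells of cluster 10. They put 95.9% of mutant SV cells of cluster 32 with cluster 4, so they do not show whether the gains in clusters 32, 38 and 49 are real.

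**Figure D2:**
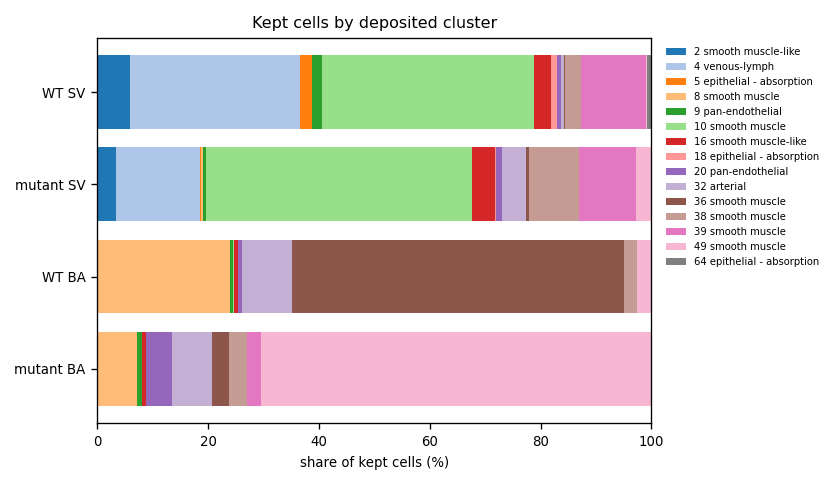
Share of kept cells (%) in each deposited cluster, 1 bar per library. Cluster 36 takes 60.1% of WT BA and cluster 49 takes 70.4% of mutant BA, while cluster 10 takes 38.3% of WT SV and 48.0% of mutant SV.

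The first comparison asks how cluster 10, the main muscle-named cluster of the SV, differs in the mutant. It is deposited as smooth muscle and has acta2 at high levels, but the genes that lead it include the striated-muscle genes atp2a1, mylpfa, ACTC1, desma and tnnt2a. In this cluster (2928 mutant and 2667 WT cells), the fibrillar matrix list had a median above 0 and the inflammation list a median below 0 in mutant over WT SV. fn1b, a fibronectin gene, was at 2779 against 580 CPM (4.80-fold, 4.71 to 4.88), and cfd, complement factor D, at 6573 against 1105 CPM (5.95-fold, 5.87 to 6.03). The chaperone gene hsp70.1 was at 9447 against 1432 CPM (6.59-fold). thbs4b, a thrombospondin gene, was at 24.1 against 371 CPM (15.4-fold lower, 14.3 to 16.7), and lacc1 at 12.3 against 287 CPM (23.3-fold lower). cfd also reached 4529 CPM in mutant and 1491 CPM in WT cells of cluster 4, so part of its signal lies outside cluster 10.

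Other genes named as higher in mutant cluster 10 were cyp2n13 (11.4-fold), coch (10.6-fold), atp5mea (8.03-fold), map1ab (5.87-fold) and cyp2ad2 (5.06-fold). The cell-cycle inhibitor gene cdkn1a was 4.57-fold higher, the complement gene c7a 4.49-fold, the aggrecan gene acana 4.33-fold and the cardiac troponin gene tnnt2a 4.12-fold. The lower side held the actin genes ACTC1 (76.3 against 580 CPM, 7.61-fold) and acta1b (4.09-fold), the chemokine gene cxcl8a (69.0 against 375 CPM, 5.44-fold) and the cytokine gene tnfb (5.38-fold). It also held hspb9, s100a11, CAMK2N1, mrpl38, adprhl1 and igfbp2a, between 4.30-fold and 7.13-fold lower.

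Of 33 measured inflammation genes in cluster 10, 16 were at least 2-fold lower and 4 higher in the mutant, with a median of -0.93 (percentile 0). The chemokine gene cxcl18b was at 1522 against 5722 CPM and the NF-kappaB inhibitor gene nfkbiaa at 573 against 1919 CPM, while the chemokine gene ccl25b was higher, at 8715 against 2909 CPM. Interferon and antigen presentation genes had a median of -0.71, with 10 of 27 lower and 4 higher, among them irf1b at 81.2 against 285 CPM. Fibrillar collagen and interstitial matrix genes had a median of 0.70 (percentile 100), with 7 of 23 higher and 1 lower, including pcolcea at 902 against 394 CPM. Of 19 cardiomyocyte sarcomere genes 12 were higher and 3 lower, with a median of 1.58. Cardiomyocyte markers over all kept cells of the library were at 308 against 133 CPM in mutant and WT SV. Those markers include tnnt2a, a leading gene of cluster 10, and the kept cells include cluster 10. The library sum is therefore not a measure separate from this cluster. Markers of immune cells, summed over all kept cells of the library, were lower in mutant SV as well: macrophage markers at 324 against 495 CPM, neutrophil markers at 558 against 974 CPM and T or NK cell markers at 10.7 against 22.2 CPM. The smooth muscle contractile list stood near 0, at -0.17, with acta2 at 12484 against 17162 CPM. The heat-shock and immediate-early list was at 0.02.

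The sarcomere median turned to -0.25 when an ambient RNA profile was subtracted, and the matrix median was 0.34 with no minimum of counts. The median of all genes in this comparison was 0.16.

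In the endothelial cluster 4 (919 mutant and 2133 WT cells), the median of flow-responsive genes was below 0 in mutant over WT SV, while those of pan-endothelial genes (median 0.010) and venous and lymphatic genes (0.079) stayed near 0. cldn5b, a tight junction gene of blood vessels, was at 636 against 49.7 CPM (12.8-fold, 11.9 to 13.7). The coagulation factor gene f8 was 6.55-fold higher and lpl, lipoprotein lipase, 6.24-fold higher. Both, like cpamd8 named below, are leading genes of arterial cluster 32, which held 4.34% of mutant and 0.617% of WT SV cells. Whether the mix of cells within cluster 4 differs was not tested. klf2b, a transcription factor gene induced by flow, was at 55.9 against 274 CPM (4.91-fold lower, 4.47 to 5.39), and lyve1a, a lymphatic marker, at 92.5 against 357 CPM (3.85-fold lower). ifitm1, an interferon-induced membrane protein gene, was at 280 against 1991 CPM (7.12-fold lower, 6.84 to 7.42).

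Further genes named as higher were mhc1uba (59.8-fold), a major histocompatibility gene, atp5mea (9.36-fold), uchl1 (9.11-fold), hsp70.1 (7.16-fold), mfge8b, cpamd8, cited4b, mpp2b and crip2 (4.66-fold). Those named as lower were igfbp1b (21.2-fold), fhl1a (8.06-fold), nts (7.51-fold), ecscr (6.24-fold), nupr1b (6.23-fold) and tnfb (5.55-fold), and hsd3b7, mgll, syne1b and cremb at 4.09-fold to 4.35-fold.

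Of 12 basement membrane genes in cluster 4, 5 were higher and 1 lower, with a median of 0.74; the laminin-binding nidogen gene nid1a was at 32.7 against 10.0 CPM and col4a2 was 2.45-fold higher, at 44.2 CPM in mutant cells. Fibrillar collagen and interstitial matrix genes had a median of 0.59 (7 of 22 higher, 2 lower), arterial genes 0.50 (4 of 14 higher, 0 lower, with dll4 at 92.2 against 44.5 CPM) and fatty acid genes 0.55 (6 of 17 higher, 3 lower). Flow-responsive genes had a median of -0.52 (1 of 16 higher, 4 lower, percentile 0.05), with klf2a at 432 against 940 CPM but edn2 at 887 against 232 CPM. Proliferation genes had a median of -0.69, at low counts. Of 32 inflammation genes 13 were lower and 3 higher, with a median of -0.66, which turned to 0.32 when an ambient profile was subtracted. The scavenger chemokine receptor gene ackr3b was higher, at 827 against 183 CPM.

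In the 4 other muscle-named clusters of the SV, the inflammation median was below 0 and the fibrillar matrix median above 0 in mutant over WT. Cluster 38 (549 mutant and 198 WT cells) had lacc1 at 3.71 against 156 CPM (42.1-fold lower), thbs4b 7.92-fold lower, the lysyl oxidase gene loxa 6.76-fold lower, and tnfb and ptges 5.61-fold and 4.51-fold lower. Higher there were mhc1uba (62.5-fold, 17.2 to 518, from 2 WT counts), neu3.2 (52.8-fold, 14.5 to 438), ITLN1 (0 WT counts, at least 32.9-fold), atp5mea (23.4-fold) and wfdc2 (15.3-fold). Its inflammation median was -0.92 (4 of 28 higher, 10 lower) and its fibrillar matrix median 0.24 (5 of 24 higher, 1 lower). Its endocardial and valve median was 0.46 and its arterial median 1.07, the latter -0.16 with no minimum of counts. Endothelial markers were higher too, with vwf at 40.65 against 3.605 CPM and cdh5 at 18.37 against 4.325 CPM. How much of the last 2 medians is endothelial RNA was not tested. In clusters made anew, 33.2% of mutant and 13.6% of WT cells of this cluster went with cluster 10, and 61.7% and 81.3% with cluster 39, so the cells compared differ in mix; of the 549 mutant cells, 440 were not marked as doublets. Cluster 39 (636 and 822 cells) had ptges 9.11-fold, igfbp1b 6.37-fold, apof 5.54-fold, mrpl38 4.27-fold and nfkbib 4.08-fold lower. ITLN1 (at least 154-fold), mhc1uba (124-fold, 42.0 to 603), neu3.2 (34.3-fold), atp5mea (28.3-fold) and cyp2n13 (9.57-fold) were higher. Its medians were -0.45 for inflammation (5 of 29 higher, 7 lower), -0.65 for hypoxia and glycolysis, 0.74 for fatty acid handling and 0.40 for fibrillar matrix.

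In cluster 16 (247 and 214 cells) 13 of 22 fibrillar matrix genes were higher and 0 lower, with a median of 1.06, such as col1a2 at 632 against 214 CPM. The lysozyme gene lyz was at 1.39 against 293 CPM (211-fold lower, 96.7 to 577), and ntmt1, mrpl38, lacc1 and ckmt1 were 16.6-fold, 7.69-fold, 7.55-fold and 6.07-fold lower. Higher were mhc1uba (107-fold), sncga (62.6-fold), the haptoglobin gene hp (23.5-fold), atp5mea (15.3-fold) and prx (14.6-fold). Its inflammation median was -0.70 (3 of 28 higher, 11 lower), and its cartilage median of 1.54 was -0.54 with no minimum of counts. In cluster 2 (211 and 419 cells) ptges, edil3a, cldn7a, sult2st1 and tmsb2 were 5.77-fold to 10.2-fold lower. ITLN1 (at least 81.9-fold), mhc1uba (63.9-fold), mhc2dab (62.9-fold), neu3.2 (29.3-fold) and atp5mea (14.6-fold) were higher. Its medians were -0.62 for inflammation (1 of 25 higher, 10 lower), which turned to 0.29 with ambient RNA subtracted, -0.65 for hypoxia and 0.44 for fibrillar matrix.

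**Figure D3:**
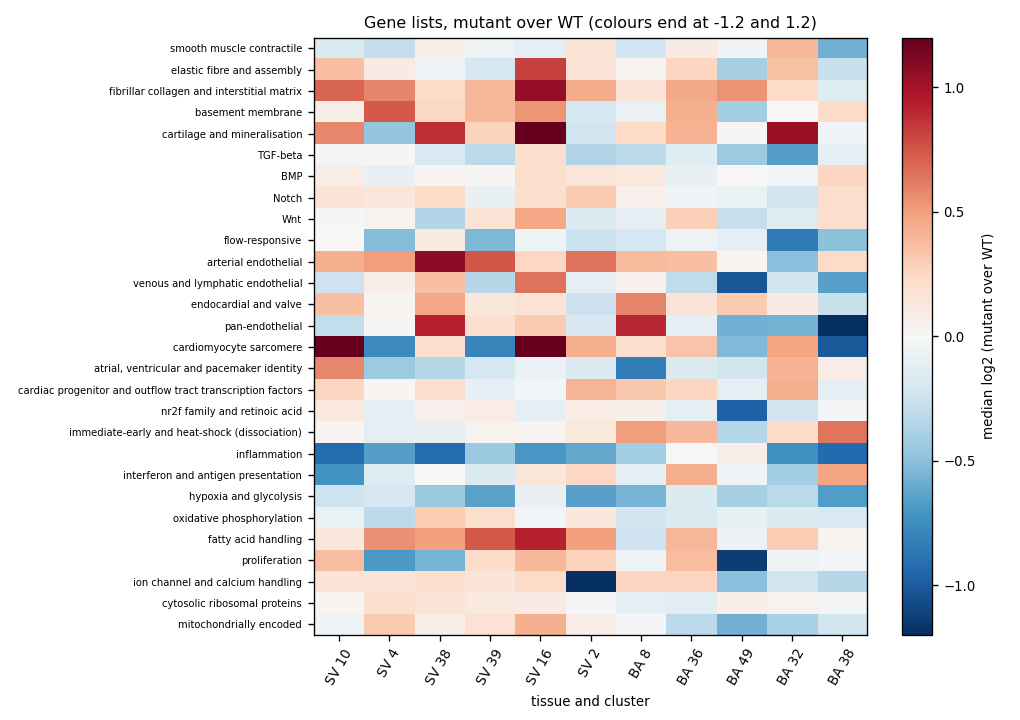
Median log2 ratio of mutant over WT for each gene list (lines) in each tissue and cluster (columns), red for higher and blue for lower in the mutant, with colours ending at -1.2 and 1.2. Inflammation was lower in SV cluster 10, at -0.93, and in BA cluster 38, at -0.93.

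The next comparison asks for the same genotype contrast in the BA. The chaperone gene hsp70.1 was higher in mutant cells of each of the muscle clusters 8, 36 and 49. In cluster 8 (540 mutant and 2073 WT cells) hsp70.1 was at 12022 against 1127 CPM (10.7-fold, 10.5 to 10.8), and her4.1 at 804 against 79.3 CPM (10.1-fold, 9.53 to 10.8). her4.2, her4.4, hspa8b, hsp90aa1.1, cited4b and cdkn1a were 4.74-fold to 7.58-fold higher. sez6a (5.05 against 95.9 CPM, 19.0-fold) and ccn2b (11.0-fold), a matricellular growth factor gene, were lower, as were cox6a2, sort1a, ctsba, tfpi2, bach1b and lmcd1 (3.21-fold to 4.06-fold). The heat-shock and immediate-early list had a median of 0.50 in cluster 8 (7 of 38 higher, 0 lower), while jun was at 1406 against 819 CPM and fosab at 2789 against 2775 CPM. Its endocardial and valve median was 0.59, hypoxia and glycolysis -0.56 and inflammation -0.42.

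In clusters 36 and 49 the mutant and WT cells are far apart in number, at 225 against 5219 and 5235 against 220. In clusters made anew, 93.3% of mutant cells of cluster 36 went with cluster 49 and 74.1% of WT cells of cluster 49 with cluster 36. The fewer cells thus went with a main cluster of their own library. Whether they stand for its muscle cells was not tested. Median depths in cluster 49 were 7959 and 5106 UMIs in mutant and WT. In cluster 36, plcd1b (36.5-fold), the lipid transporter gene abcg1 (28.4-fold), hsp70.1 (15.97-fold), mmel1, cited4b, ccl20b, dnajb1b and mgp (7.11-fold) were higher. cox5b2 (9.47-fold), ankrd22, tfpi2, rasgef1ba, sema4ba, dhfr, loxl2b and dkk3b (4.92-fold) were lower. In cluster 49, ccl20b (27.7-fold, 10.8 to 102), cited4b (14.6-fold), ca10a (10.0-fold), admb, hsp70.1 (5.58-fold), cdkn1a, atp5mea and agtr2 were higher. cox5b2 (14.9-fold), mrap2a, loxl2b, rasgef1ba, dhfr, pdk2b, itpk1a and aste1a (5.05-fold) were lower. The heat-shock list was at 0.39 in cluster 36 and at -0.34 in cluster 49, where fosab was lower, at 2511 against 9867 CPM. The fibrillar matrix medians were 0.46 and 0.54; the latter was -0.20 with no minimum of counts. The medians of all genes were 0.25 and -0.24.

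In the arterial cluster 32 of the BA (541 mutant and 774 WT cells) her4.1 was at 229 against 2.12 CPM (108-fold, 64.1 to 198) and her4.2 at 80.5 against 0.758 CPM (106-fold, 45.4 to 328). stmn4l, hsp90aa1.1 (28.5-fold), cyp2ad2, the adrenomedullin gene admb (18.8-fold), hapln1a (17.5-fold), a gene of proteoglycan linkage, and gch2 were also higher. Of these genes, her4.1, her4.2, stmn4l and hapln1a are leading genes of muscle cluster 8, and gch2 of muscle cluster 49. The muscle gene myh11a was higher in cluster 32 too, at 354 against 130 CPM. Whether muscle RNA or mixed cells bring these genes to cluster 32 was not tested. ecscr, an endothelial surface gene, was at 25.9 against 322 CPM (12.4-fold lower), and clu at 210 against 1463 CPM (6.97-fold lower). tp53inp1 (15.01-fold), loxl2b, ptges, efna1b, gmppb and tnfaip2b (5.86-fold) were lower too. TGF-beta genes had a median of -0.66 (0 of 22 higher, 9 lower), flow-responsive genes -0.84 and inflammation genes -0.74, while the heat-shock list was at 0.23. Pan-endothelial genes were lower as well, with a median of -0.56 over the 21 genes also measured in SV cluster 4. The smooth muscle contractile list was at 0.40 (4 of 21 higher), such as tagln at 692 against 210 CPM; median depths were 10385 and 5550 UMIs, and the value was 0.09 in thinned cells, 0.92 without doublets and 2.41 with ambient RNA subtracted. The cartilage median of 1.03 was -0.78 with no minimum of counts.

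In cluster 38 of the BA (235 and 201 cells) heat-shock genes were higher, with a median of 0.64 (13 of 38 higher, 0 lower), hspa1b at 257 against 11.0 CPM and hsp70.1 at 9085 against 521 CPM. mhc1uba (at least 36.13-fold) and ITLN1 (at least 29.6-fold) had 0 WT counts, and cyp2n13 was 14.7-fold higher. Contractile genes were lower (0 of 19 higher, 5 lower, median -0.57), with acta2 at 1547 against 4277 CPM, and kcne4, a leading gene of muscle cluster 36, was at 424 against 3086 CPM. In clusters made anew, 69.7% of WT cells of this cluster went with cluster 36 and 76.2% of mutant cells stayed with cluster 38, so the cells compared may differ in type. gem (15.4-fold), dhfr, rab5if, ptges and c7b (64.0 against 467 CPM, 7.30-fold) were lower. Inflammation had a median of -0.93 and hypoxia and glycolysis of -0.67.

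The tissue comparison in WT asks which genes distinguish outflow from inflow. Clusters 8, 36 and 49 of WT BA (7512 cells) were set against cluster 10 of WT SV, since the tissues share almost no muscle cluster; the genes named therefore include some that define these clusters. itih1, a protease inhibitor heavy chain gene, was at 849 against 0.720 CPM (1179-fold higher in BA, 746 to 1990), the titin gene ttn.2 at 210 against 1.08 CPM (194-fold), and the transcription factor gene sox6 72.9-fold higher. adarb1a, cracr2b, crip2, trim55b and ppl were 93.6-fold to 297-fold higher. Higher in the SV were sost, a Wnt inhibitor gene, at 333 against 0.523 CPM (638-fold, 449 to 939), csrp1b at 1082 against 6.75 CPM (160-fold) and thbs4b (139-fold). angptl1a, gucy1a1 and enpep were 654-fold to 1101-fold higher in the SV, and mylpfa (2608-fold, 721 to 21549) and alx4b (1937-fold, 535 to 16008) rested on 2 BA counts each.

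Cartilage and mineralisation genes were higher in BA muscle (9 of 13 higher, 1 lower, median 2.23), such as acana at 294 against 12.9 CPM. Basement membrane genes were lower (1 of 15 higher, 10 lower, median -1.81, with col4a2 at 10.6 against 57.1 CPM), as were inflammation genes (21 of 35 lower, -1.48), Wnt genes (12 of 21 lower, -1.43) and nr2f and retinoic acid genes (9 of 18 lower, -1.004). The elastin gene elnb was at 279 against 106 CPM. The cartilage median was 1.34 in thinned cells and 0.17 with no minimum of counts. The median of all genes was 0.22.

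Arterial cluster 32 of WT BA was set against venous-lymph cluster 4 of WT SV. The aquaporin gene aqp8a.1 was at 1417 against 3.51 CPM (404-fold, 318 to 522), and cyp1b1, kcnk4a, gpd1b, sat1a.1, the netrin gene ntn1a, adarb1a and f8 were 49.04-fold to 242-fold higher in the BA. csf1b had 0 BA counts (at least 1099-fold lower), and the lymphatic and sinusoidal genes lyve1b (1 BA count, 1467-fold, 263 to 57951), stab2 (186-fold) and lyve1a (78.4-fold) were lower. So were cxcl18a.1 (1 count, 1910-fold, 343 to 75436), igfbp1b (1 count, 461-fold, 82.7 to 18235), ccl20b (226-fold) and thy1 (66.4-fold). Arterial genes had a median of 1.64 (9 of 17 higher, 2 lower), venous and lymphatic genes of -2.23 (1 of 16 higher, 12 lower), fibrillar matrix genes of 1.25, contractile genes of 1.12 and cartilage genes of 3.91. The median of all genes was -0.35. The muscle gene acta2 was at 639 CPM in WT BA cluster 32 (55.2% of cells) and at 215 CPM in WT SV cluster 4 (47.3% of cells). How much of the matrix, contractile and cartilage medians is RNA of muscle cells was not tested.

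In cluster 38, present in both tissues (201 BA and 198 SV cells), acana (47.8-fold, 16.1 to 234, from 3 SV counts), gem (1 count, 111-fold, 19.6 to 4424), ccn2b (34.2-fold), the Wilms tumour gene wt1b (27.2-fold) and ccl20b (23.3-fold) were higher in WT BA. neu3.4 (0 counts, at least 67.4-fold), smoc1 (2 counts, 74.5-fold, 20.2 to 622), ptn (2 counts, 64.5-fold, 17.4 to 540), alx4b (1 count, 112-fold, 19.5 to 4459) and neu3.5 (41.0-fold) were lower. Contractile genes had a median of 0.91 (8 of 19 higher, 0 lower), heat-shock and immediate-early genes of -1.14 (0 of 38 higher, 20 lower) and nr2f and retinoic acid genes of -1.66. In clusters made anew, 69.7% of these BA cells went with muscle cluster 36 and 81.3% of these SV cells with cluster 39, so the cells compared may differ in type.

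The same tissue contrast was made in the mutants. In muscle, itih1 was at 669 CPM in mutant BA against 14.5 CPM in mutant SV (46.0-fold), and rock2b, ttn.1, her4.2 and the transferrin gene tfa were 23.3-fold to 38.3-fold higher in the BA. alx4b (773-fold), angptl1a (589-fold), enpep (394-fold), csrp1b (248-fold) and sost (213-fold) were higher in the SV. Medians were 1.92 for cartilage, -2.23 for basement membrane, -1.50 for nr2f and retinoic acid and -0.92 for fibrillar matrix genes; the cartilage value was -0.11 with no minimum of counts. In endothelial clusters, gpd1b (197-fold), gch2 (194-fold), adarb1a, kif26ba and hapln1a (1 count, 489-fold, 87.5 to 19346) were higher in the BA. nr2f1a was at 0.0881 CPM in mutant BA cluster 32 (1 count) against 78.7 CPM in mutant SV cluster 4 (893-fold, 160 to 35323). lyve1b (456-fold), stab2 (334-fold), cxcl18a.1 (3 counts, 902-fold, 308 to 4376) and csf1b (0 counts, at least 584-fold) were higher in the SV. Contractile genes had a median of 2.01, elastic fibre genes of 1.75 and venous and lymphatic genes of -1.78. The median of all genes was -0.37. The muscle gene tagln was at 692 CPM in mutant BA cluster 32 and 164 CPM in mutant SV cluster 4. hapln1a and gch2 are leading genes of muscle clusters 8 and 49. How much of the differences in these genes and in the contractile and elastic fibre lists is RNA of muscle cells was not tested. In cluster 38, ccn2b (57.5-fold), ccl20b, lum, itga8 and cemip (5.23-fold) were higher in the BA. crhbp (3 counts, 329-fold, 112 to 1595), sost (89.5-fold), neu3.5, nts and neu3.2 (29.3-fold) were higher in the SV. There, nr2f and retinoic acid genes had a median of -1.49; the pan-endothelial median of -1.11 was 0.05 without doublets and 1.61 with ambient RNA subtracted, and the median of all genes was -0.18.

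The genotype effect in the SV was then set against that in the BA, as a difference of log2 ratios with an interval for counting error only. Clusters 8, 36 and 49 of the BA were summed for this, a choice made after the data were seen. In muscle, itih1 differed by 4.68 (4.0 to 5.36), at 14.5 against 0.720 CPM in the SV and 669 against 849 CPM in the BA, and fn1b by 2.75. itih1 was seen in 5.26% of mutant SV cluster 10 cells. Free RNA or mixed cells of the BA cannot be told apart from a change of expression at that level. The heat-shock gene dnajb1b differed by -2.44, at 3248 against 2072 CPM in the SV and 4240 against 499 CPM in the BA. The fibrillar matrix list differed by 0.70 and the heat-shock list by -0.40, which were 0.13 and -0.08 when the BA clusters were weighted to 1 mix. In cluster 38 the heat-shock list differed by -0.82 and thbs4b by -3.63. In endothelial cells the basement membrane list differed by 0.78, and her4.1, a leading gene of muscle cluster 8, by -6.03. Across genes, which are not replicates, Spearman correlations of both effects were 0.474, 0.386 and 0.435 for muscle, cluster 38 and endothelial cells.

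The last comparison asks where mutant SV lies relative to WT SV and WT BA. WT SV cells were split at random into parts A and B; part A against WT BA defined BA-high and SV-high genes, and mutant SV was measured against part B. In muscle, 305 BA-high genes had a median log2 ratio of 0.36 (0.32 to 0.37; 45 at least 2-fold higher, 10 lower) and 233 SV-high genes of -0.43 (-0.45 to -0.41), while all genes of this comparison had a median of 0.17. cfd (6573 CPM in mutant SV, 1182 in part B, 7647 in WT BA), acana, crip1, alcama and matn4 were among the BA-high genes that were higher. lacc1, thbs4b, ACTC1 and cxcl8a were among the SV-high genes that were lower, as were the inflammation genes tnfb, cxcl18b and nfkbiaa. The inflammation list was also lower in mutant than in WT BA muscle. Over genes measured in both tissues its median was -0.44 in the BA and -0.99 in the SV. A fall of such genes therefore does not by itself place mutant SV nearer to the BA. With lists made from the mutant libraries alone, the muscle medians were 0.48 and -0.06. In cluster 38 the medians were 0.31 (211 genes) and -0.49 (213 genes), and 0.064 over all genes. In clusters made anew, 69.7% of WT BA cells of cluster 38 went with cluster 36 and 81.3% of WT SV cells with cluster 39. Of its SV cells, 33.2% in the mutant and 13.6% in WT went with cluster 10. Whether this mix of cells gives the shift in cluster 38 was not tested.

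In endothelial cells the medians were 0.12 (254 genes) and -0.35 (296 genes), and 0.055 over all genes. cldn5b (636 CPM in mutant SV, 54.0 in part B, 428 in WT BA), f8 and lpl were BA-high genes that were higher, and ifitm1 (280, 2063 and 261 CPM), nts and igfbp1b were SV-high genes that were lower. The endothelial BA-high median turned to -0.05 under median-of-ratios scaling. Slopes of the mutant effect on the tissue effect were 0.160, 0.222 and 0.109 for muscle, cluster 38 and endothelial cells. Noise of the WT SV library that is not counting noise enters both sides.

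**Figure D4:**
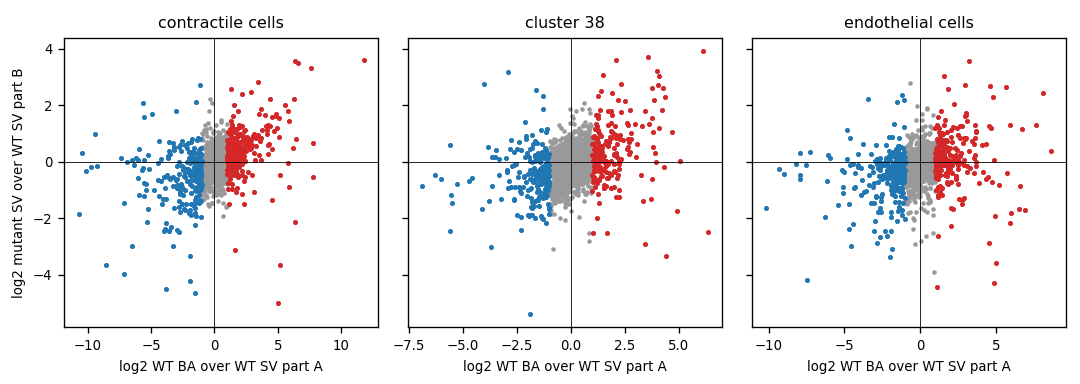
Log2 ratio of mutant SV over part B of WT SV (vertical axis) against log2 ratio of WT BA over part A (horizontal axis), 1 point per gene, in muscle, cluster 38 and endothelial cells. Red points are BA-high genes, blue points SV-high genes and grey points other genes; muscle medians are 0.36 and -0.43.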

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

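The tests named here were chosen only after the result was seen: both tests of nr2f1a, the look at its level in other clusters, and the limits, narrower than those first tried, that single out genes and lists whose genotype effects are opposite in the SV and the BA.

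nr2f1a also appeared in barcodes that the comparisons do not use. Outside the deposited cluster table, mutant SV held 388 nr2f1a UMIs (21.4 CPM) and WT SV 104 (4.80 CPM), a 4.45-fold difference (3.58 to 5.58). Endothelial markers were also higher in those mutant SV barcodes, at 696 against 229 CPM, so the barcodes compared differ in content.

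Within the kept cells, nr2f1a in mutant SV cluster 10 may be carried there as free RNA of endothelial cells, where it is highest. The genes cdh5, kdrl, vwf, egfl7, clec14a and tie1 stood in mutant cluster 10 at 1.77% of their level in cluster 4, which predicts 1.39 CPM of nr2f1a. The level found was 22.7 CPM, 16.3 times the predicted one, which argues against that source. In thinned cells the mutant to WT ratio was 2.7 against 2.34 in all cells. CPM is already relative to the summed UMIs, so this ratio cannot decide on a difference in depth. Depth can change the share of cells with an nr2f1a UMI. In thinned cells of cluster 10 that share was 6.59% in mutant SV (5.68 to 7.59%) and 2.43% in WT SV (1.86 to 3.115%). The share was thus higher in the mutant at equal depth too. Other clusters of mutant SV differ: the epithelial cluster 5 held 21.1 CPM (6.85 to 49.2) and clusters 38, 39 and 2 held 20.02, 25.5 and 33.2 CPM, near the level of cluster 10, the first from 5 UMIs. Cluster 16 held 2.54 CPM (1.27 to 4.55) and cluster 49 held 11.9 CPM (7.05 to 18.8). Cluster 18, deposited as epithelial but with the thyroid follicular marker tg among its leading genes, held 0 UMIs in 20 cells (0 to 11.4 CPM). These levels lie below cluster 10 (21.03 to 24.5 CPM), which argues against free RNA spread alike over all clusters. How much of it is free RNA stays open, as does an effect of the genotype, which the design names but 1 library per group leaves untested.

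Some genes had effects of opposite direction in the 2 tissues, each by at least 1 on the log2 scale; these differences, given as SV effect minus BA effect, were not tested. In muscle, crip1 differed by 3.52 (161.6 against 52.5 CPM in the SV, 323 against 1204 CPM in the BA). spaca4l differed by 3.45 (11.0 against 2.60 CPM in the SV) and ptgis by 3.32 (6.58 against 2.36 CPM in the SV). thbs4b differed by -6.20 (24.1 against 371 CPM in the SV, 12.7 against 2.67 CPM in the BA). her4.2 differed by -3.70 (2.08 against 5.24 CPM in the SV) and the desmin gene desma by -2.77 (2.84 against 1.23 CPM in the BA). How much of these low levels is free RNA or mixed cells was not tested, so an opposite effect is not shown for such genes. The BA side sums clusters 8, 36 and 49, whose mix differs between the libraries; with 1 mix these differences were 3.07, 2.31, 2.80, -7.28, -3.88 and -2.99 in the order given. In cluster 38, wt1b differed by 4.92 (28.9 against 2.88 CPM in the SV, 26.0 against 78.4 CPM in the BA), crhbp by 4.91, spaca4l by 4.11, LRATD2 by 3.26 and aoc2 by -2.55. In endothelial cells, cldn5b differed by 5.01 (636 against 49.7 CPM in the SV, 170 against 428 CPM in the BA), crlf1a by 3.92 and slc43a2b by 3.30. There, ifitm1 differed by -3.95, cxcl14 by -3.48, syt4 by -3.46 and mgll by -3.27.

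Lists were singled out where the median log2 ratios over the genes measured in each tissue were opposite, each by at least 0.4; the differences, taken over genes measured in both tissues, were not tested. The atrial, ventricular and pacemaker identity list (0.58 in the SV, -1.40 in the BA) differed by 2.92 in muscle over 9 genes; over these its medians were 0.27 and -1.70, and the latter and the difference are those of nr2f1a itself, a gene of the list at 1.54 CPM or less in BA muscle. The pan-endothelial list (0.93 and -1.56) differed by 1.67 in cluster 38 over 8 genes, with medians of 0.16 and -1.56 over these. In endothelial cells the cartilage list (-0.46 and 1.03) differed by -0.60 over 3 genes, with an interval that includes 0 (-1.27 to 0.03), and the arterial list (0.50 and -0.50) by 0.65 over 13 genes. Over those shared genes neither endothelial list had opposite medians: they were -0.23 and -0.086 for cartilage, 0.59 and 0.088 for arterial genes.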

How the results depend on the processing

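Alternatives chosen only after the data were seen were the doublet rule by score rank, the sum of clusters 8, 36 and 49, and nr2f1a without cluster 20; the rest were planned. No paired analysis was possible because each group had 1 library and no test was made. Over 390 results, 4067 alternative values were computed, each set against the interval of its main value, or for counts of genes against a 1.5-fold range. Among genes and lists named in passing, 2956 values stayed within it, 835 left it and 8 were counted as turned. Among the values that answer a comparison, 172 stayed within it, 92 left it and 4 were counted as turned. Not every change of sign was counted as turned, so the values that stayed or left may include further changes of direction. For all values given here the cause was not tested. Leaving out cells over 10% mitochondrial UMIs took 361 values of the first kind and left each within its interval. A minimum of 1000 UMIs removed no kept cell, and shares without blood cells gave no value, since no deposited cluster is of blood. Of the 250 named genes, 226 were named again without doublets, 185 in thinned cells and 180 with ambient RNA subtracted, but only 132 at a minimum of 10 CPM and 81 at 200 CPM. Few cells limit the counts of cluster 38 of the SV and clusters 36 and 49 of the BA.

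Under TMM scaling, medians were 0.57 for fibrillar matrix in SV cluster 10, 0.37 for heat-shock in BA cluster 8, 0.27 and -0.51 for BA-high and SV-high genes in muscle, -0.39 for SV-high genes in cluster 38, 0.016 and -0.43 for BA-high and SV-high genes in endothelial cells, and 0.59 for the fibrillar matrix difference between tissues. Under median-of-ratios scaling they were -1.08 for inflammation and 0.54 for fibrillar matrix in SV cluster 10, 0.35 for heat-shock in BA cluster 8, 0.27 and -0.52 in muscle, -0.047 (turned) and -0.50 in endothelial cells, and 0.62 for the fibrillar matrix difference. Without haemoglobin, mitochondrial and ribosomal protein genes, SV-high medians were -0.40 in muscle, -0.35 in cluster 38 and -0.29 in endothelial cells, and the endothelial BA-high median was 0.21. As a mean over cells, inflammation in SV cluster 10 was at -1.09, the contractile list in BA cluster 32 at 0.57 and SV-high genes in cluster 38 at -0.31.

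In thinned cells, inflammation and fibrillar matrix in SV cluster 10 were at -1.11 and 0.61, the contractile list in BA cluster 32 at 0.087, cartilage between WT tissues at 1.34, cluster 38 at 0.19 and -0.28 for BA-high and SV-high genes, endothelial cells at 0.17 and -0.31, and the fibrillar matrix difference at 0.56. Without doublets, the contractile list in BA cluster 32 was at 0.92, cartilage between mutant tissues at 2.35, SV-high genes in cluster 38 at -0.38, endothelial BA-high and SV-high genes at 0.18 and -0.36, cluster 4 at 16.04% of mutant SV cells, and the pan-endothelial list between mutant tissues in cluster 38 turned to 0.051. With ambient RNA subtracted, inflammation was at -1.28 in SV cluster 10 but turned to 0.32 in cluster 4 and to 0.29 in cluster 2, cardiomyocyte sarcomere genes in SV cluster 10 turned to -0.25, and the pan-endothelial list in cluster 38 turned to 1.61. Heat-shock in BA cluster 8 was then at 0.44, the contractile list in BA cluster 32 at 2.41, cartilage between mutant tissues at 2.54, cluster 38 at 0.16 and -0.27, endothelial SV-high genes at -0.16, the heat-shock difference at -0.57 and nr2f1a in cluster 4 at 1.59 (log2).

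In random parts of the cells, inflammation was at -1.25 in SV cluster 10 and -0.90 in cluster 4, cartilage at 1.44 between WT and 1.46 between mutant tissues, muscle BA-high genes at 0.38 and 0.32, SV-high genes at -0.55 in cluster 38 and -0.37 in endothelial cells. With clusters weighted to the same mix, cartilage between mutant tissues was at 1.53, muscle BA-high and SV-high genes at 0.43 and -0.46, and the fibrillar matrix and heat-shock differences at 0.13 and -0.082. With no minimum of counts, fibrillar matrix in SV cluster 10 was at 0.34, inflammation in cluster 4 at -0.34, heat-shock in BA cluster 8 at 0.54 and cartilage between WT tissues at 0.17. That setting turned cartilage between mutant tissues to -0.11, arterial genes in SV cluster 38 to -0.16, cartilage in SV cluster 16 to -0.54 and in BA cluster 32 to -0.78, and fibrillar matrix in BA cluster 49 to -0.20. At a minimum of 100 counts, cartilage between WT tissues was at 2.95.

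With lists made at 4-fold, BA-high and SV-high medians were 0.67 and -0.54 in muscle and 0.72 and -0.54 in cluster 38, and SV-high genes were at -0.43 in endothelial cells. With mutant BA defining the lists they were 0.63 and -0.58 in muscle, 0.77 and -0.71 in cluster 38, and 0.54 and -0.49 in endothelial cells. In that setting an effect shared by both mutant libraries enters both sides, so these medians can be larger for that reason alone. Over 20 other splits, BA-high medians ran from 0.32 to 0.38 in muscle, 0.18 to 0.41 in cluster 38 and 0.098 to 0.20 in endothelial cells, and SV-high medians from -0.46 to -0.39, -0.50 to -0.30 and -0.36 to -0.31. Over all barcodes, nr2f1a in mutant over WT SV was at 1.04 (log2), and without cluster 20 nr2f1a in mutant over WT BA turned to -0.63 (log2). Own clusters gave cluster 32 as 0.0287% of WT and 0.0655% of mutant SV cells, cluster 4 as 33.9% and 20.6%, cluster 49 as 0.0144% and 0.164%, and cluster 10 as 55.0% of mutant SV cells.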

Other observations

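Of the tests given here, those of mixed cells, diluted SV-high genes, shared barcodes and doublets were chosen only after the result was seen, as was the set of comparisons used for shared genes.

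Across 9 genotype comparisons (clusters 10, 4, 38 and 39 of the SV and 8, 36, 49, 32 and 38 of the BA), 7 genes with at least 50 CPM on 1 side were at least 2-fold higher in the mutant in each and 3 at least 2-fold lower in each. The higher ones were the chaperone genes hsp70.1 (median log2 2.84), stip1 (1.54) and fkbp4 (1.23), cdkn1a (2.24), cited4b (2.92), uchl1 (1.95) and 1 gene known by a clone name. The lower ones were the annexin gene anxa1a (-1.23), the tubulin gene tuba8l4 (-1.30) and another clone name. Other hsp70 genes did not follow hsp70.1 in each comparison. In SV cluster 38, hsp70l was at 23437 against 28749 CPM and hsp70.3 at 11935 against 11194 CPM in mutant and WT. In BA cluster 38 both were higher, at 25448 against 8798 CPM and 12741 against 3370 CPM. Whether reads are shared among these copies was not tested. These 9 comparisons come from 2 pairs of libraries, so a change of a whole library, or its free RNA, recurs in each of its clusters, and how many such genes chance would give was not computed. The histocompatibility gene mhc1uba was higher in mutant cells in each of these 9 and in SV clusters 16 and 2, though its low WT counts (0 in BA clusters 49 and 38) would also follow from an allele that the reference does not match, which was not tested.

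Barcodes outside the deposited table held markers of blood: erythrocyte markers came to 98358 CPM in WT BA and 91405 CPM in mutant BA, but to 1397 CPM in WT SV and 169 CPM in mutant SV. Hepatocyte markers came to 19895 CPM in mutant SV against 2052 CPM in WT SV. Cardiomyocyte markers came to 2480 CPM in mutant SV against 1143 CPM in WT SV. Neuron markers were at 302 CPM in mutant SV, 5.49 CPM in WT SV, 1.70 CPM in WT BA and 1.76 CPM in mutant BA.

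In mutant SV muscle over part B of WT SV, there was a gap of 0.79 between BA-high and SV-high medians. Noise of the WT SV library shared by both sides could give such a gap, but lists made from the mutant libraries alone kept a gap of 0.55, with medians of 0.48 and -0.06, so the SV-high side lost most of its size. RNA or cells of the BA would have to make up 25.8% of the RNA to lower SV-high genes by their median, 5.37 times the upper bound of the excess in BA-high genes that WT SV lacks (1.38% of the WT BA level, 0.223 to 4.79%), which argues against them for the SV-high side. For the BA-high side, free RNA and mixed BA cells cannot be told apart from a change of expression: the excess was 4.99 times larger in genes that WT SV also has, past the bound of 3 written in advance, but that bound ignored the shift of all genes and the spread over 14 genes (1.202 to 30.9, from resampling genes), and the ratio was 1.498 with all genes centred. Own clusters led by cluster 8, 36 or 49 held 0.0342% of mutant SV cluster 10 cells, but also just 5.71% of the mutant SV cells deposited as 8, 36 and 49, so they decide nothing, and genotype, library and batch stay confounded.

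Clusters 8, 36 and 49, made mostly of BA cells, held 210 mutant SV cells. BA tissue carried over at dissection could bring such cells: SV-high genes stood in mutant SV cluster 49 at 9.18% of their cluster 10 level, 4.96 times their share in cluster 4, which passes the bound of 3 written in advance against carry-over. That bound was too simple, because a mix of carried-over BA cells and SV cells placed there would pass it too, and itih1 was seen in 65.6%, csrp1b in 27.0% and both in 20.9% of the 163 cells of cluster 49 (median 8805 UMIs), against csrp1b in 8.92% of mutant SV cluster 4 (9021 UMIs) and 2.87% of mutant BA cluster 49 cells (7959 UMIs) and itih1 in 5.26% of mutant SV cluster 10 cells (9896 UMIs). This reading was made after those cells were examined, so carry-over and SV cells cannot be told apart here; 83.8% of the 210 cells fell in own clusters led by cluster 10, which split by library. Barcodes shared with BA cells (0.476%) are argued against. Doublets were marked among the 210 cells at 0.635 times the rate of the library. That score cannot decide on doublets of an SV and a BA cell, because it was computed within the SV library, where cells of BA type are few.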
